A study of Morella rubra with 12 samples.

How the data were processed

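RNA was extracted with Trizol from frozen fruits of Chinese bayberry (Morella rubra) and sequenced on Illumina libraries, per the labels' protocols. The 12 libraries comprise 3 of BDK fruits at each of 55, 70 and 85 days after flowering (stages 1, 2 and 3) and 3 of DK fruits at 85 days. Groups and replicate numbers were taken from the sample titles and the days from the series' design text.

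Per the file headers, the authors deposited 1 FPKM value per gene and library, written to 2 decimals, for 119701 genes. The gene IDs have the form of genes of a de novo transcript assembly. The assembler, the aligner or quantifier, the annotation and any filter are not given in the sources used here. FPKM divides a gene's fragments by its length and by the library's fragments, so a few very abundant transcripts lower all other values of a library. The summed FPKM ran from 817744 to 1219280, so the libraries were not on 1 common total.

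The values were used as deposited for levels and shares. For tests, trimmed-mean scaling factors (30% of log ratios and 5% of mean levels trimmed at each end, over genes of at least 1 FPKM in both libraries) were computed on FPKM and ran from 0.912 to 1.12. Genes with at least 1 FPKM in at least 3 libraries were kept, 23074 in all. Log2(FPKM / factor + 1) was modelled with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level. All 12 libraries and 4 groups entered 1 model without covariates, and 4 comparisons were drawn from it. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and an adjusted p below 0.05 counts as called. Fold changes on this scale understate the change of low genes. Where a gene is listed at 0 in all libraries of a group, each library's value is given and no fold.

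The comparisons, scaling method, threshold, alternatives and rule for naming genes were set before the data were examined. The count test planned then could not be run, because the files hold FPKM only. Limma on log2(FPKM + 1), planned as an alternative, took its place. The filter of 1 FPKM, the unweighted trimming on FPKM and the use of this model for all results were set after the values had been seen, and numbers of calls under 4 scalings and with the replicate number in the model had been printed before the final settings were written. Trimmed-mean scaling was kept because the plan named it.

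Genes are named by a fixed rule: for each comparison the 2 that rose and the 2 that fell with the largest absolute log2 change among called genes with a mean of at least 10 FPKM in the higher group and no overlap between the 2 groups' libraries. The plan set that minimum on normalised counts. The files do not pair IDs with names, so the planned tests of gene lists (anthocyanin, ethylene, cell wall, sugar and other pathways) were not run. Genes of 1 assembly cluster, whose IDs start alike (c55062_g1 and c55062_g4), can share reads, and their separate levels are uncertain.

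The procedure was tested on simulated data built from the real genes' levels and spread, with 100 genes changed 2-fold and 100 changed 4-fold among 23074. For stage 2 against stage 1 it recovered 82% and 98% of them in the right direction, for stage 3 against stage 2 87% and 97%, for stage 3 against stage 1 80% and 98%, and for DK against BDK 88% and 97%. Between 8 and 12 unchanged genes were called. Only genes with a mean level above about 10 FPKM over all libraries were changed. These shares are therefore no measure of recovery for lower genes, among them those near the filter of 1 FPKM. Far fewer genes were changed than the 8567 to 12916 called between BDK stages. Recovery with that many changed genes was not tested.

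The files hold no counts, so no counting interval can be given. Relative depth was estimated from the steps that 1 read makes in low values (0.3 to 1.5 FPKM), as the most frequent log2 ratio between pairs of libraries, and ran from 0.822 to 1.22. No 2 libraries were copies: at most 11.9% of tested genes had equal values in a pair.

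The overlap of the strain comparison with ripening was set against independent lists (the product of both counts over the genes tested). For the last BDK step, which shares the BDK stage 3 libraries, 20 simulated sets of unchanged groups, disjoint BDK stage 3 libraries and a projection on an axis built without the library projected were added. The library set was found by counting, after the data were seen, which genes lie above 0 in which libraries. It entered as a model term and through fits of each set alone, in which a group with 1 library adds nothing to the estimate of spread and is assumed to vary like the other groups.

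Alternatives planned before the data were examined were median-of-ratios and upper-quartile factors, no factors, no filter, the replicate number as a block, a 2-fold minimum, only the 2 groups compared, and each library left out in turn. Chosen after seeing the data were pseudocounts of 0.1 and 5, a filter of 5 FPKM in place of the stricter count filter, no variance trend, and the library set.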

Results

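Transcript levels were measured by RNA sequencing in fruits of Chinese bayberry (Morella rubra), a tree grown for its juicy stone fruits. Fruits of the pale strain Baidongkui (BDK, whose fruits the title calls pink-white and the colour label pink) were sampled at 3 stages, 55, 70 and 85 days after flowering. Ripe fruits of the red cultivar Dongkui (DK, colour label black) were sampled at 85 days. Each of the 4 groups holds 3 libraries. The labels do not say whether these came from separate trees or fruits, so the p-values measure the spread between these samples, which may be technical.

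Each library lists an FPKM value (fragments counted on a gene, normalised to its length and to the library's size) for the same 119701 assembled genes, of which 101724 lie above 0 in at least 1 library and 23074 were tested. The libraries list between 32084 genes (DK replicate 2) and 48737 genes (BDK stage 1 replicate 3) above 0. The files hold no read counts, so the total depth is unknown. Relative depth, read from the smallest steps between low values, ran from 0.822 in DK replicate 2 to 1.22 in BDK stage 2 replicate 2. These 2 estimates are also the least certain of the 12, with an SD of 0.27 and 0.21 on the log2 scale over the libraries they were compared with. The files do not pair the gene IDs with names, so the genes below are known by ID only and what they encode, anthocyanin genes included, was not analysed here.

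A split that crosses the labelled groups ran through the libraries. A total of 876 genes were above 0 in all 3 BDK stage 1 libraries, BDK stage 2 replicate 1 and BDK stage 3 replicates 1 and 2 (the first set), and at 0 in BDK stage 2 replicates 2 and 3, BDK stage 3 replicate 3 and all 3 DK libraries (the second set). The reverse pattern held for 120 genes, and the next most frequent pattern of 6 libraries for 80. All DK libraries lie in the second set with 1 BDK stage 3 library, and all BDK stage 1 libraries in the first, so each comparison is given also with the set as a term in the model or within a set.

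Fruit stage set the largest differences between libraries. Across the 23074 tested genes, Pearson's r between libraries of 1 group was 0.929 to 0.964 (genes are not independent replicates), and between BDK stage 1 and BDK stage 3 it was 0.766 to 0.792. BDK stage 3 and DK libraries correlated at 0.908 to 0.955, a range that overlaps the range within groups. The first principal component, with 51.0% of the variance, separated all 3 BDK stages, at -140 to -137, -0.68 to 8.57 and 56.0 to 76.1, and placed the DK libraries, at 68.4 to 72.0, inside the BDK stage 3 range. The second component, with 12.5%, placed the 3 DK libraries, at -5.37 to 22.7, between BDK stage 2, at -76.5 to -49.1, and BDK stage 3, at 34.5 to 49.6.

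**Figure D1:**
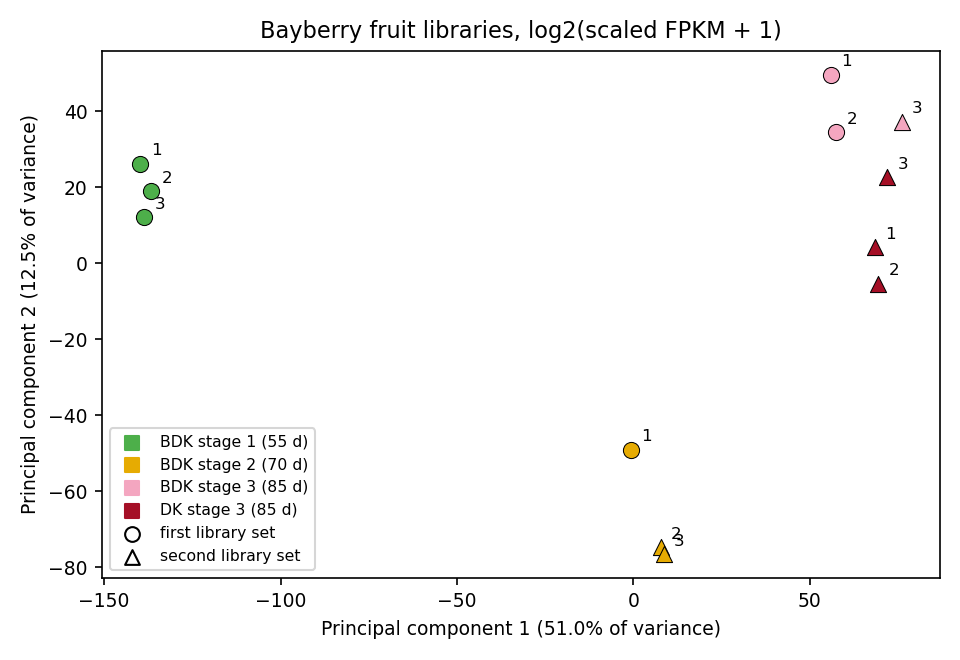
Principal components of log2(scaled FPKM + 1) over the tested genes, with component 1 (51.0% of variance) on the x axis and component 2 (12.5%) on the y axis, both in units of the log2 values. Each point is 1 library with its replicate number, coloured by group, circles for the first library set and triangles for the second, and the DK libraries lie inside the BDK stage 3 range on component 1, at 68.4 to 72.0, and between BDK stage 2 and BDK stage 3 on component 2, at -5.37 to 22.7.

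Young fruit put more of its transcripts into few genes than ripe fruit did. The 50 most abundant genes of each library held 34.7% ± 1.26 of the summed FPKM at BDK stage 1, 29.1% ± 2.26 at stage 2, 21.6% ± 1.42 at stage 3 and 20.6% ± 0.11 in DK (SD, n = 3). The ranges of the 3 BDK stages did not overlap, which with 3 libraries against 3 gives the smallest p an exact permutation test allows, 0.1 (two-sided). BDK stage 3 and DK differed by less than their spread (exact permutation test, p = 0.4). Of the 74 genes with a mean of at least 1000 FPKM at BDK stage 1, 37 were also at that level at BDK stage 3, and 19 were under 100 FPKM there. BDK stage 3 and DK shared 67 such genes, out of 74 and 83.

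The comparison of BDK stage 2 with stage 1 asks which transcripts change as the fruit develops between 55 and 70 days. Gene c55127_g1 became 1 of the most abundant transcripts of the fruit, from 41.7 ± 26.8 FPKM at stage 1 to 9771 ± 345 at stage 2 (SD, n = 3), and stayed at 10226 ± 1673 at BDK stage 3 and 10457 ± 330 in DK. Gene c12674_g1, listed at 0 in each stage 1 library, was at 478, 279.5 and 363 FPKM in the 3 stage 2 libraries. In the other direction c52028_g1 fell from 1605 ± 510 to 2.46 ± 0.58 FPKM, and c49572_g1 from 569.5 ± 320 to 0.59 ± 0.30. Neither exceeded 1.12 FPKM in any ripe library.

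On the log2(FPKM + 1) scale, which understates the change of low genes, the fitted changes were 8.18 ± 0.42 for c55127_g1, -8.70 ± 0.21 for c52028_g1 and -8.14 ± 0.42 for c49572_g1 (SE), with limma's adjusted p of 1.90e-07, 2.35e-09 and 1.85e-07. Of the genes tested, limma called 11743 (50.9%) at an adjusted p below 0.05, 5704 higher and 6039 lower at stage 2. A change of at least 2-fold was reached by 2018 of the higher and 2868 of the lower genes. The higher genes held 23.0% ± 1.08 of the summed FPKM at stage 1 and 51.7% ± 1.19 at stage 2, and the lower genes 39.8% ± 3.66 and 13.1% ± 0.51. With the library set as a term 9864 genes were called, 9619 of them among the 11743 and in the same direction, and within the first set 6554 were called, with 1 stage 2 library that is assumed to vary like the other groups' libraries. The balance of higher and lower genes depended on the scaling, at 6047 and 5683 with upper-quartile factors, 5135 and 6703 with median-of-ratios factors and 4928 and 6873 with none. Gene c12674_g1, which is also at 0 in BDK stage 3 replicate 1, had an adjusted p of 0.0095, and of 8.37e-06 to 0.080 under other settings, the highest with the set as a term.

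The comparison of BDK stage 3 with stage 2 covers the last step, from 70 to 85 days, in which the fruit ripens. Gene c50570_g1 rose from 0.34 ± 0.29 to 188 ± 107 FPKM and c50360_g1 from 0.89 ± 0.86 to 704 ± 18.1 (SD, n = 3). The latter varied at stage 1, where 1 library had 977 FPKM and the other two 0 and 0.64. Gene c50105_g1 fell throughout, from 488 ± 85.5 at stage 1 through 138 ± 40.1 at stage 2 to 0.22 ± 0.19 at stage 3. Gene c46760_g1 peaked at stage 2, with 12.9 ± 4.72, 129.0 ± 86.8 and 0.13 ± 0.09 FPKM over the 3 stages.

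The fitted log2 changes of this step were 7.06 ± 0.49 for c50570_g1, 8.77 ± 2.01 for c50360_g1, -6.75 ± 0.23 for c50105_g1 and -6.43 ± 0.57 for c46760_g1 (SE). Their adjusted p from limma were 5.48e-06, 0.0060, 1.84e-07 and 2.26e-05. In all 8567 genes (37.1%) were called, 3629 higher and 4938 lower at stage 3, of which 917 and 1565 changed at least 2-fold. The higher genes went from 16.9% ± 0.46 to 35.2% ± 0.85 of the summed FPKM and the lower genes from 35.2% ± 1.02 to 18.0% ± 0.83. FPKM as deposited, with no scaling factors, gave 2695 higher and 6068 lower, 30.8% higher against 42.4%. With the set as a term 7982 genes were called, 7750 of them among the 8567 and in the same direction. Within the second set 4905 were called, with 1 stage 3 library, and within the first set 1790, with 1 stage 2 library, the lone library being assumed to vary like the other groups' libraries. Gene c50360_g1 lost its call in 1 of its 19 other settings, the first set alone, where its log2 change was 8.15.

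The widest interval was BDK stage 3 against stage 1, from 55 to 85 days. Gene c56883_g3 fell from 6707 ± 2414 FPKM at stage 1 through 27.6 ± 4.32 at stage 2 to 5.27 ± 0.18 at stage 3 (SD, n = 3), and c47732_g1 from 2719 ± 1685 through 7.39 ± 2.99 to 2.18 ± 1.89. Gene c54611_g1 rose from 14.4 ± 6.87 through 1088 ± 156 to 6382 ± 741 FPKM, and c42284_g1 from 5.71 ± 7.57 through 975 ± 99.95 to 2973 ± 1132. In DK these 4 genes were at 3.53 ± 1.75, 4.77 ± 1.51, 4873 ± 249.6 and 2246 ± 163 FPKM in the order named.

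Their log2 changes were -9.76 ± 0.29, -9.65 ± 0.61, 9.004 ± 0.26 and 9.54 ± 0.60 (SE), with limma's adjusted p of 2.27e-09, 2.92e-07, 1.97e-09 and 3.15e-07. Of the genes tested 12916 (56.0%) were called, 5783 higher and 7133 lower at stage 3. At least 8-fold changes were made by 319 higher and 735 lower genes. The median change of all genes was -0.08 on the log2 scale and -0.26 without scaling factors, where 4347 genes were higher and 8674 lower (33.4% higher against 44.8%). With a filter of 5 FPKM the balance was even, at 5158 higher and 5159 lower. With the set as a term 12436 were called, 12215 of them shared and in the same direction, and 10405 within the first set.

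Sorting genes by their calls in both steps describes the course of ripening in BDK. The 1728 genes that fell in both steps went from 20.6% ± 1.96 of the summed FPKM at stage 1 to 6.06% ± 0.23 and 2.67% ± 0.27, and the 1496 that rose in both from 5.44% ± 0.29 to 11.2% ± 0.26 and 23.7% ± 0.54 (SD, n = 3). In addition 2565 genes rose in the first step and were not called in the second, and 3474 fell in the first and were not called in the second, a number that was 2313 without BDK stage 1 replicate 1 and 2025 with a filter of 5 FPKM. A transient peak at stage 2 was shown by 1643 genes, whose share went from 7.78% ± 0.22 to 16.1% ± 0.85 and back to 10.1% ± 0.49. A trough at stage 2 was shown by 837 genes. With a 2-fold minimum in each step called, 486 genes fell in both, 236 rose in both, 309 peaked and 117 had a trough, and with no filter on low values 1145 fell in both and 521 had a trough. Changes called in the last step alone were upward for 1296 genes and downward for 1567 (564 and 770 with the 2-fold minimum, which left 1473 and 2265 genes called in the first step alone), and 8468 genes (36.7%) were called in neither step. In total 5704 genes were called in both steps, 4739 with the set as a term and 1148 where both changes had to reach 2-fold.

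**Figure D2:**
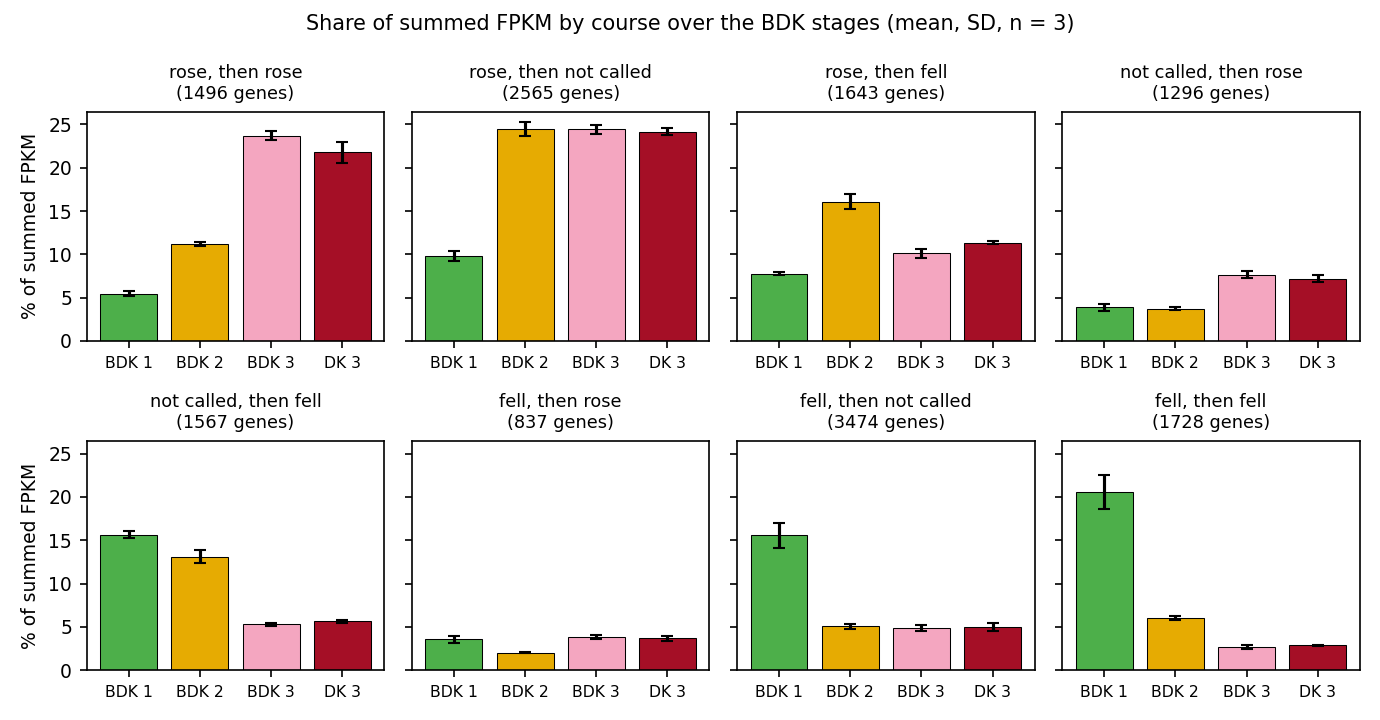
Share of the summed FPKM (y axis, percent) held by 8 classes of genes, sorted by their calls in the step from BDK stage 1 to 2 and then from stage 2 to 3, in the 4 groups on the x axis. Bars are means of 3 libraries and error bars the SD, and the genes that fell in both steps drop from 20.6% at BDK stage 1 to 2.67% at BDK stage 3 while those that rose in both climb from 5.44% to 23.7%.

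The comparison of DK with BDK at 85 days asks how ripe red fruits differ from ripe pale ones. Gene c107382_g1 was at 336 ± 9.30 FPKM in DK and 2.68 ± 1.24 in BDK (SD, n = 3), a 126-fold ratio of means. In BDK this gene declined with stage, from 62.5 ± 3.34 at 55 days through 22.0 ± 9.89 at 70 days, so that DK held more of it than any BDK stage. Gene c21337_g1 was at 51.0 ± 25.9 FPKM in DK and at 0, 5.61 and 0 in the BDK stage 3 libraries, but at 47.2 ± 6.38 in BDK stage 2. Lower in DK were c102955_g1, listed at 0 in all 3 DK libraries and at 25.5, 11.1 and 20.5 FPKM in BDK stage 3, and c55062_g4, at 0, 0 and 44.6 FPKM in DK and 144 ± 78.0 in BDK stage 3.

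The log2 differences, DK minus BDK, were 6.58 ± 0.28 for c107382_g1 and 4.69 ± 0.67 for c21337_g1 (SE), with limma's adjusted p of 9.43e-06 and 0.0051. For c102955_g1 the adjusted p was 0.011. For c55062_g4, at -5.26 ± 1.30, it was 0.042, and 11 of the 18 other settings tried gave a value above 0.05, over a range from 0.0012 to 0.31 (0.0012 without DK replicate 3, 0.18 with the library set as a term). This gene shares an assembly cluster with c55062_g1 (looked up after its values were seen), which was at 0 in BDK stage 3 and 8.63 FPKM in DK on average, so reads could have been divided between them and its level is uncertain.

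Far fewer genes differed between the strains than between stages. Limma called 1503 (6.51% of those tested), 755 higher and 748 lower in DK, of which 197 and 168 differed at least 2-fold and 12 and 5 at least 8-fold. The higher genes held 6.20% ± 0.36 of the summed FPKM in DK and 3.48% ± 0.47 in BDK, the lower genes 3.08% ± 0.12 and 5.10% ± 0.10. The groups did not overlap for 25.2% of the genes tested, where chance gives 10%, and 5210 genes had an unadjusted p below 0.05. With the library set as a term 542 genes were called, 284 higher and 258 lower, 488 of them among the 1503 and in the same direction, and all 1503 kept their sign. The term raised the median SE from 0.177 to 0.214, and the log2 differences with and without it correlated at r = 0.84 across genes. Of 242 genes called for the set, 0 were among the 1503. However, 210 of the 242 were at 0 in all second-set libraries, which splits the BDK stage 3 libraries. Such a split widens the spread in the model without the term and hinders a strain call. The 0 is therefore no evidence that the strain calls are free of the set. Why the count fell was not tested. Within the second set 411 were called, where BDK stage 3 has 1 library, whose spread is not measured and is taken from DK and BDK stage 2, so this count is no independent check. The count fell to 737 without BDK stage 3 replicate 1, to 596, 632 and 764 without DK replicate 1, 2 or 3, to 595 with only these 2 groups in the model and to 346 with no filter on low values.

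**Figure D3:**
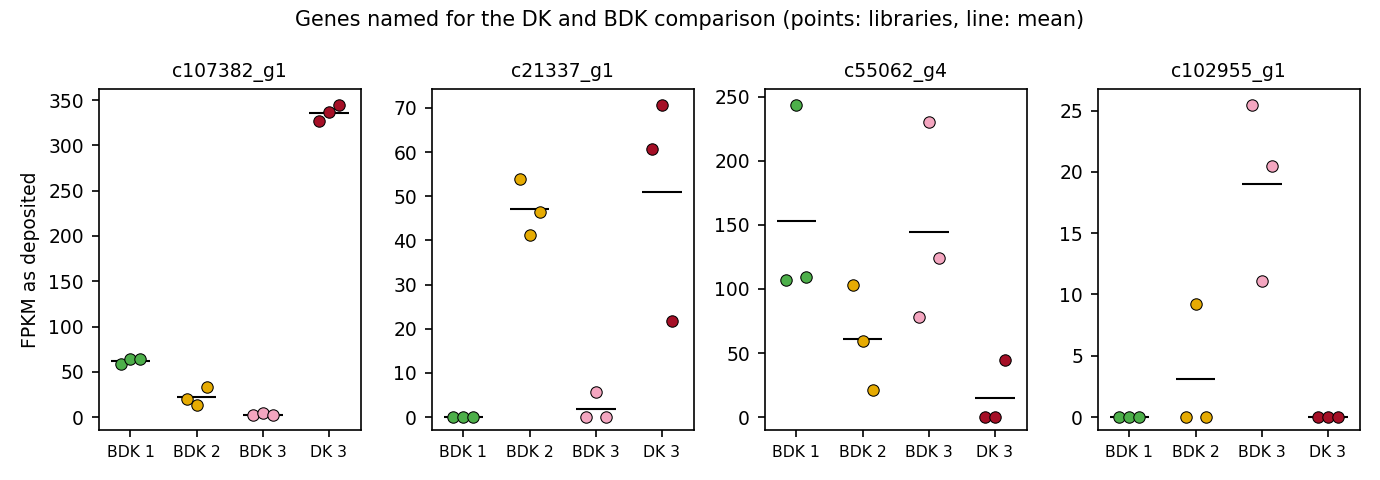
FPKM as deposited (y axis, linear, a scale for each gene) of the 4 genes named for the comparison of DK with BDK at 85 days, in BDK stages 1 to 3 and DK on the x axis. Points are libraries and lines the means of 3, and c107382_g1 stands at 336 FPKM in DK against 62.5, 22.0 and 2.68 in the BDK stages.

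The genes that set DK apart were compared with those that change as BDK ripens. For the first step, which shares no library with the strain comparison, 530 genes were called in both and in the same direction and 468 in opposite directions, where independent lists would give 382 and 383. Independent lists take every gene to be as easily called, so an excess in both directions is alone no link between strain and ripening. Strain calls covered 1.88% of the genes called in neither BDK step and 3.91% to 16.5% of the other classes. Which direction was more frequent was not stable, with 712 alike and 740 opposite without BDK stage 3 replicate 2, and 71 and 71 with at least 2-fold changes. The log2 changes correlated across genes at r = 0.12. With the set as a term the counts were 167 and 153. Without DK replicate 1, 2 or 3 they were 207 and 187, 214 and 195, or 254 and 226, and without BDK stage 3 replicate 1 they were 263 and 234. Without BDK stage 3 replicate 3 they were 461 and 294.

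For the last step the directions were mostly opposite. Of the genes called in both, 452 were higher in DK and fell in BDK from 70 to 85 days, 468 were lower in DK and rose in BDK, and 137 went the same way in both, so 87.0% were opposite. Independent lists would give 279 opposite and 279 alike. Of the 1496 genes that rose in both BDK steps, 182 were lower in DK and 38 higher, and of the 1643 that peaked at stage 2, 170 were higher in DK and 14 lower. With the set as a term 375 were opposite and 42 alike, and with at least 2-fold changes 194 and 14. Without DK replicate 1, 2 or 3 the opposite genes numbered 375, 398 or 492, and without BDK stage 3 replicate 1 or 2 they numbered 477 or 1429.

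Both of these comparisons use the BDK stage 3 libraries, which pulls their changes apart with no effect present. The log2 changes correlated at r = -0.44 across genes with a covariance of -0.21, and 20 simulated sets of unchanged groups gave on average r = -0.50 and a covariance of -0.068. Unchanged groups give almost no calls, so they offer no reference for the 920 opposite genes. The covariance beyond the simulated one was -0.14. The simulation cuts values at 0, which can narrow its noise and so overstate this excess. With different BDK stage 3 libraries on each side, the covariance itself, with nothing subtracted, ran from -0.15 to -0.067. Along the axis from BDK stage 2 (0) to BDK stage 3 (1), built without the library it was applied to, the BDK stage 3 libraries lay at 0.876 ± 0.061 and the DK libraries at 0.752 ± 0.023 (SD, n = 3). The difference of -0.12 had the smallest p that a permutation test of 3 against 3 allows, 0.1 (two-sided). That p is approximate, as each BDK value comes from its own axis while each DK value is a mean over 3 axes, which also narrows the DK spread. On single axes the DK values ran from 0.705 to 0.833, and on each axis they lay below the BDK library left out. They were at 0.770 to 0.833 against 0.911 without BDK stage 3 replicate 1, and at 0.705 to 0.739 against 0.806 without replicate 2. The 0.833 exceeds that 0.806, but the 2 values come from different axes. The 3 axes share libraries, so they are not independent. On the axis built without BDK stage 3 replicate 3, that library lay at 0.912 and the DK libraries at 0.729, 0.743 and 0.761. All of these are second-set libraries, but the stage 3 end of that axis is the first-set libraries, so this is no check within a set.

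**Figure D4:**
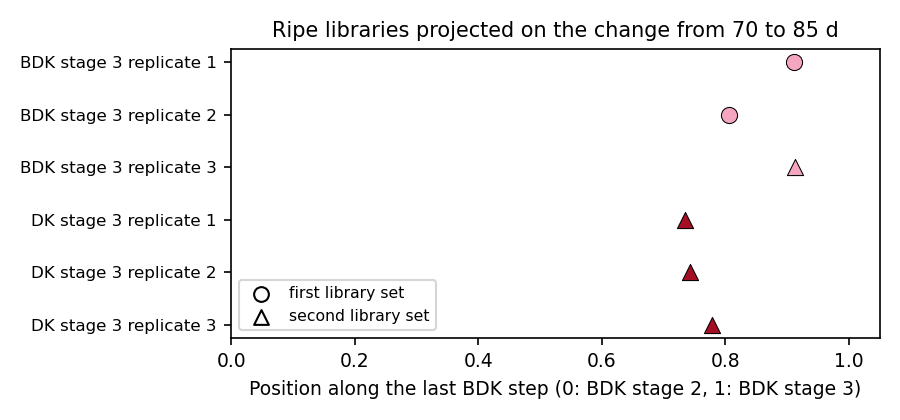
Position of each ripe library along the change from BDK stage 2 (0) to BDK stage 3 (1) on the x axis, a unitless projection over the genes called in that step, with 1 library per line, circles for the first library set and triangles for the second. Each BDK library was left out of its own axis and each DK value is the mean over the 3 axes, and the 3 DK libraries, at 0.735 to 0.778, lie below the 3 BDK libraries, at 0.806 to 0.912.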

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

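The pseudocounts, the 5 FPKM filter, the model without variance trend and those using the library set were chosen after seeing the data. The count tests, the stricter count filter, the minimum gene length and the gene list tests were not run, as the files hold no counts, lengths or names. Of 285 values of named genes under other settings, all kept their direction and 272 their call. Of the 13 others, 11 belong to c55062_g4. The 285 leave out the 2-fold minimum and the settings in which the filter dropped a named gene, so the 272 cover only settings where a gene was tested. Gene c49572_g1 was dropped whenever a BDK stage 1 library was left out. Genes c102955_g1 and c46760_g1 were dropped within the second set, and c12674_g1 and c50570_g1 within the first. Requiring 2-fold changes left 4886, 2482 and 6470 genes for stage 2 against 1, 3 against 2 and 3 against 1, 365 for DK against BDK, 1148 called in both steps, 71 shared with the first step in the same direction (and 71 opposite) and 194 opposite to the last. Within the first set 6554 and 1790 genes were called for the first 2 comparisons (10405 for the third), and within the second 4905 for stage 3 against 2 and 411 for DK against BDK; fewer libraries enter these fits, and the lone library of a group is assumed to vary like the others. For DK against BDK the set term gave 542, no filter 346 (more genes share the adjustment) and the 2 groups alone 595. The overlaps became 167 and 375 with the set term and 98 and 224 with no filter, and the first 351 without the variance trend; the cause was not tested. Leaving out 1 library at a time gave 596 to 2138 genes for DK against BDK, 207 to 712 for the overlap with the first step (740 opposite at the highest, without BDK stage 3 replicate 2) and 375 to 1429 opposite to the last. It moved the calls of no stage comparison by more than 1.5 times, but the genes that fell and then were not called went from 3474 to 2313 without BDK stage 1 replicate 1.

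The replicate numbers were not taken to pair samples: residuals of the 18 same-number pairs correlated at -0.15 to 0.17, 1 of them above 0.1, and 6 of 12 libraries correlated best with their own number. How many would do so without pairing was not computed. The highest residual correlation between groups, 0.25, was of libraries with different numbers, BDK stage 2 replicate 1 and DK replicate 3. With the replicate block 11612, 8337, 12805 and 1115 genes were called, and it ended the call of c55062_g4. Depth limits low genes, for which the value of 1 read is unknown.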

Other observations

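Apart from the splits of libraries given last, the tests in this part were chosen after the result was seen. Some genes were listed in a single group. Above 0 in all 3 libraries of a group and at 0 in the other 9 were 1069 genes for BDK stage 2, 360 for BDK stage 1, 49 for DK and 21 for BDK stage 3. Any 3 of the 12 libraries make 220 trios, of which the median trio had 17 such genes, and as many as DK were found in 38 of them and as many as BDK stage 2 in 1. The next highest trio crosses groups, BDK stage 2 replicates 2 and 3 with DK replicate 2, and had 818, more than BDK stage 1. The reverse, genes listed in all 9 BDK libraries and at 0 in all 3 DK libraries, held for 74 genes, a number reached by 2 of the 220 trios. Of the very abundant genes (at least 1000 FPKM), 10 of the 74 at BDK stage 3 and 14 of the 83 in DK were under 100 FPKM at BDK stage 1.

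The first pattern is the opposite direction of the strain difference and the last ripening step, 920 genes against 137. That noise of the shared BDK stage 3 libraries is the whole source is argued against by the covariance, which stayed below 0 with different libraries on each side, -0.067 at its nearest to 0. This removes the noise of single libraries only. A level particular to BDK at stage 3 would still enter both comparisons with opposite signs, and the position along the BDK axis has the same limit. The library set as the whole source is argued against by the model that includes it, where the covariance lay below that expected from noise of the shared libraries by a difference of -0.085, and at -0.14 to -0.021 with 1 library left out, nearest to 0 without BDK stage 3 replicate 3, the only BDK library of that stage in the second set. A candidate explanation is that DK fruits at 85 days were less far along the same course, with a mean position of 0.752 against 0.876 for BDK, but no earlier DK stage was analysed here, and a lasting difference between the strains in the same genes cannot be told apart from slower ripening. With 3 libraries a group the approximate permutation p was 0.1, and DK was not behind along the first principal component, which also orders the BDK stages (68.4 to 72.0 in DK, 56.0 to 76.1 in BDK stage 3). On the second component DK, at -5.37 to 22.7, lay between BDK stage 2, at -76.5 to -49.1, and BDK stage 3, at 34.5 to 49.6. That component does not order the stages, as BDK stage 1, at 12.1 to 26.2, also lay between them.

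The second pattern is the 876 genes listed in 1 set of 6 libraries and at 0 in the other. Lower depth of the libraries at 0 is argued against by their 1-read steps, whose median differed by -0.10 on the log2 scale, toward greater depth. Regulation by stage or strain alone would leave the replicates of a stage interchangeable, but of the 1212 genes listed in all BDK stage 1 libraries, no DK library and only replicate 1 of stage 2, 72.3% were listed in exactly replicates 1 and 2 of stage 3, against 3.39% and 3.17% of those listed only in stage 2 replicate 2 or 3. That 72.3% is the 876 genes of the pattern, so the share restates how the pattern divides replicates of a stage and is no separate test. RNA that came with a set of libraries, by handling or processing, may be the source: over the 170 of these genes at 1 FPKM or more in all 6 libraries, the change from BDK stage 1 to stage 3 had an SD of 0.33, where 1000 lists of genes at matched levels and under the same minimum had a median of 0.82 and a 5th percentile of 0.72. Whether it came from another organism or from a difference in the authors' processing stays open.

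The third pattern is BDK stage 1 replicate 3, which lists 8884 genes found in no other library, against 1120 to 5215 in the others. Greater depth is argued against by its relative depth, 0.97 of the other BDK stage 1 libraries. RNA of another organism or tissue is possible, as these genes hold 10.6% of its summed FPKM against 1.98% to 7.77% elsewhere, but it cannot be told apart from other sources without sequences. No biological explanation was tested, as the labels set this library apart from its group in nothing.

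The 6 libraries of each comparison make 10 splits into 3 and 3, too few for a share under 0.05. The real split alone reached its own count, 1 of 10, with 11743, 8567, 12916 and 1503 genes for stage 2 against 1, 3 against 2, 3 against 1 and DK against BDK, where the highest of the other splits gave 24, 272, 22 and 18. Each other split mixes libraries of both groups, so a real difference adds to the spread, and these low counts are no reference for unchanged groups.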
